A study of Gallus gallus with 6 samples.

How the data were processed

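The series holds 6 RNA sequencing libraries of hen jejunal mucosa, 3 from control hens at 23 °C and 3 from hens held at 36 °C for 6 h. Per the labels' protocols, RNA of 4 hens was pooled for each library, from 12 hens per group, and libraries were made after poly(A) selection or ribosomal RNA removal. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, the tools were cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2, with the genome build GRCg6a. The notes give no order or settings for these tools.

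The authors deposited 1 table of 16317 genes with gene symbols and NCBI gene identifiers. It holds an estimated count per gene and library, per the file headers and the values: between 13.05% and 13.65% of the values of each library are not whole numbers within 0.001. The tool that made these estimated counts is not given in the sources used here. The table also holds FPKM values, which the authors deposited per the file headers. The gene length implied by count, library total and FPKM was used as gene length, and 99.7% of tested genes had one. The symbols of 20 genes had been turned into dates, and all 20 were named through their gene identifier in a reference gene table of another assembly (GRCg7b), which matched 15169 identifiers (93.0%). No coordinates are given for that reason. Reads of near-identical genes, such as heat shock paralogs, could have been split between copies by the counting, so single members of such families are uncertain. The strand setting of the counting is not given in the sources used here.

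The design fixed before the data were examined foresaw limma-trend on log2(FPKM + 1), and edgeR instead if the table held raw counts. The table held estimated counts, and whether these meet the plan's condition of raw counts is open. They were rounded to whole numbers and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. Results of limma-trend on log2(FPKM + 1) are given beside it. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and p-values were adjusted after Benjamini and Hochberg, two-sided. SE is the absolute log2 fold change divided by the square root of the F statistic. The threshold was an adjusted p of 0.05, and an added count used an absolute log2 fold change of at least 1. CPM values use the TMM scaled library sizes. The common biological coefficient of variation was 0.196. Python 3.11.15 with pandas 2.3.3 prepared the table and matplotlib 3.10.9 drew the plots.

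Gene lists were fixed before the data were examined. There were 33, of which 31 had at least 5 tested members. The list of the mitochondrial genome had 0 members in the table and the exocrine pancreas list had 4 tested members (0 past the threshold over the list alone, median 0.18), so neither was tested as a list. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and beside it with an estimated correlation and with fry. With fry, 0 lists passed, and fry's mixed test, for changes in either direction, passed for 9 lists: clock (adjusted p 0.00174), erythroid (0.00436), cell cycle (0.00758), hypoxia and glycolysis (0.00758), antioxidant (0.0386), glucocorticoid (0.0386), sterol synthesis (0.0439), lipid absorption (0.0453) and proteasome (0.0475). It did not pass for chaperones (0.108) or interferon response (0.112). Members were also adjusted over the list alone.

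The genes named in the text followed a rule fixed in advance. It took the genes past the threshold whose pools did not overlap (up to 10 per direction), or the 5 with the smallest p where none passed in a direction. It added up to 4 members with the smallest p of each list, and always HSPA2, HSPA8, HSPH1, HSP90AA1, HSP90AB1, DNAJA1, BAG3, HSPB9, HSP25, HSPA5 and HSF1 where measured. HSP25 was not analysed here. Genes outside this rule, such as DNAJA4, are named where a count of 5 or fewer needed them, after their values were seen. Some genes that the rule names are not reported here.

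The summed counts of 11513427 to 13805395 per library set the counting error. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom from 21.3 to 62.7), so no library had been deposited more than once within its group. Pairs across the groups were not compared in this way. The tests were checked on simulated counts with the real means and library sizes of 3 and 3 libraries, in which 100 genes differed 2-fold and 100 differed 4-fold. Over 12961 genes, edgeR recovered 60% of the 2-fold and 94% of the 4-fold changes with 10 false calls. Over 13060 genes, DESeq2 recovered 73% and 96% with 49 false calls. Each gene was drawn independently, with a dispersion estimated from the real libraries, so genes did not vary together and no simulated pool stood apart. These shares need not hold for the real libraries.

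Alternatives planned in advance were other scalings, other filters, edgeR without an abundance trend or with robust moderation, a replicate block, DESeq2 1.42.0, a threshold of 0.1, leaving out each library in turn, and limma on log2 FPKM with other pseudocounts (0.1 and 0.5), filters, scalings and variance models. Limma-trend on log2(FPKM + 1) itself was the plan's test for a table without raw counts. Alternatives chosen after seeing the data were a mean FPKM of at least 1, library totals without TMM, voom with library quality weights and removal of a loess trend on gene length. So were the list results without heat pool 2, and camera with an estimated correlation without each library in turn and without the length trend.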

Results

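Messenger RNA was measured by RNA sequencing in the jejunal mucosa, the lining of the middle part of the small intestine, of SUT breeder hens aged 28 weeks. The design compared hens kept at 23 °C with hens held at 36 °C for 6 h, to find genes that respond to acute heat in the gut. Of 50 hens, 25 were kept under each condition and 12 per condition were sampled. RNA of 4 hens was mixed in each pool, which gave 3 control pools and 3 heat pools, each sequenced as 1 library. Replicates are therefore pools of separate hens, and the spread between them is a spread between pools. The summed estimated counts were 13805395, 13542604 and 13633493 in control pools 1, 2 and 3 and 11513427, 12775927 and 12947832 in heat pools 1, 2 and 3. Between 14871 and 15136 genes had at least 1 count in a library, and 13060 genes had enough counts to be tested.

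After 6 h at 36 °C, 3 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and all 3 rose. OSGIN1 (gene 415706), an oxidative stress induced growth inhibitor, went from 115 ± 7.73 to 305 ± 36.9 CPM (library-size scaled counts; mean ± SD, n = 3 pools), a log2 fold change of 1.41 with SE 0.13 and an edgeR adjusted p of 0.0312. IRS2 (gene 101749060), an adaptor of the insulin receptor, went from 28.5 ± 3.37 to 75.6 ± 6.57 CPM, a log2 fold change of 1.41 with SE 0.13 and an edgeR adjusted p of 0.0312. CYP2U1 (gene 422528), a cytochrome P450 that hydroxylates fatty acids, went from 60.1 ± 2.21 to 131 ± 13.1 CPM, a log2 fold change of 1.12 with SE 0.11 and an edgeR adjusted p of 0.0348. All 3 rose by more than 2-fold, with every heat pool above every control pool.

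No gene passed in the lower direction in edgeR, which counted 0, against 1178 lower and 1159 higher at an unadjusted p under 0.05. DESeq2 called 277 lower and 338 higher, and limma-trend on log2(FPKM + 1) called 29 lower and 12 higher. The 5 genes with the smallest p in that direction each had an edgeR adjusted p of 0.0773 and did not pass. They were APEH, an enzyme that releases acetylated residues from peptides, at a log2 fold change of -1.16 (SE 0.14), the gene listed as ODF3L15 at -0.90 (SE 0.12), and CAD, which starts pyrimidine synthesis, at -0.97 (SE 0.13). The others were RRM1, the large subunit of ribonucleotide reductase, at -0.99 (SE 0.13), and GBP7, a guanylate-binding protein, at -1.93 (SE 0.27). In 24.46% of tested genes the 3 heat pools lay all above or all below the 3 control pools (1509 higher and 1685 lower), where chance gives 10%. The count of 3 was 0 without any single control pool and without heat pool 1, was 3 without heat pool 2 (OSGIN1, DNAJA4 and NDRG1) and was 7 without heat pool 3.

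Heat shock chaperones, which refold damaged proteins, were higher in heat pools as a group. Of 39 tested members, 31 had a positive fitted change. In edgeR none passed over all genes (12 rose in DESeq2), and 18 rose with adjusted p under 0.05 adjusted over the list alone, as counted by edgeR here and below. The median log2 fold change was 0.68, and the gene set test camera gave an adjusted p of 1.28e-06 with its preset correlation and an adjusted p of 0.998 with an estimated correlation. Without heat pool 2 the median was 0.40. DNAJA1, a co-chaperone of HSP70, was at 1.17 (SE 0.22, edgeR adjusted p = 0.0803 over all genes), and FKBP4, a co-chaperone of HSP90, at 0.97 (SE 0.19, edgeR adjusted p = 0.0897). The cytosolic HSP90 gene HSP90AA1 was at 2.15 (SE 0.46) and HSPH1, of the HSP110 family, at 2.42 (SE 0.58). HSPA8, the constitutive HSP70, was at 1.12 (SE 0.36), and its CPM went from 1782 ± 3.76 to 3873 ± 2239. Without heat pool 2 the log2 fold changes of HSP90AA1, HSPH1 and HSPA8 were 1.35, 1.31 and 0.55. The count of 18 was 0 without any single control pool, was 25, 18 and 20 (with 1, 1 and 0 lower) without heat pools 1, 2 and 3, and was 3 by limma-trend on log2(FPKM + 1).

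The size of this response differed between the heat pools. HSPB9, a small heat shock protein, was at 3.16, 1.58 and 6.28 CPM in the control pools and at 26.2, 2259 and 37.5 CPM in heat pools 1, 2 and 3. HSPA2, an HSP70 family member, was at 93.9, 79.6 and 155 CPM in the control pools and at 323, 5895 and 307 CPM in the heat pools. BAG3, a co-chaperone of HSP70, was at 69.8, 1045 and 116 CPM in the heat pools against 46.8 ± 1.74 CPM in the control pools. Their log2 fold changes of 7.72 (SE 1.92), 4.31 (SE 1.17) and 3.13 (SE 0.93) did not pass over all genes, with edgeR adjusted p of 0.124, 0.14 and 0.158. Without heat pool 2 the log2 fold changes of HSPB9 and HSPA2 were 3.12 and 1.53, and BAG3 was 2-fold higher, against 8.78-fold with all pools. Connective tissue genes also stood apart in this pool: the median of the fibroblast list lay 0.50 above the control mean in heat pool 2 and at -0.053 and -0.41 in heat pools 1 and 3 (log2 CPM). The first principal component, with 37.6% of the variance, placed heat pool 2 at 45.69 and heat pools 1 and 3 at 7.999 and 6.499. Heat pool 3 stood apart on the second (20.4%), at -38.84 against 2.7 to 13.51 for the other 5 pools. The library weights of voom were 0.505 for heat pool 3, 0.675 for heat pool 2 and 1.29 to 1.34 for the others.

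**Figure D1:**
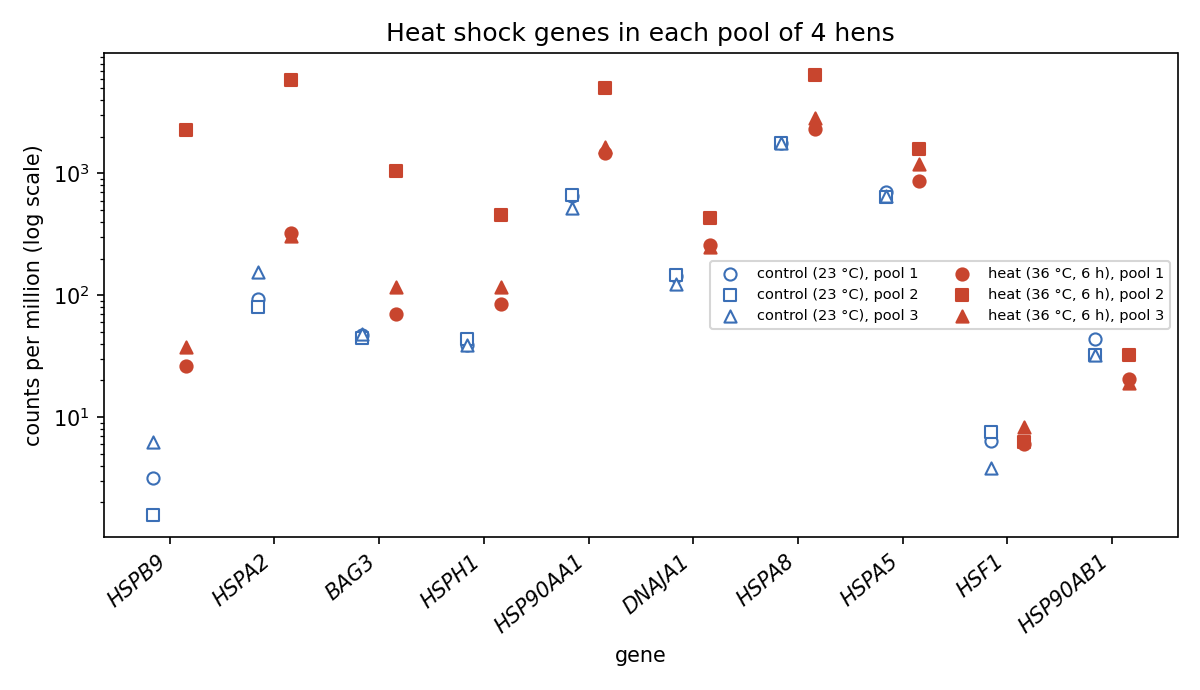
CPM (log axis) of the 10 heat shock genes chosen in advance, one point per pool, with open blue symbols for the 3 control pools and filled red symbols for the 3 heat pools. HSPA2 lies between 79.6 and 155 CPM in the control pools and at 323, 5895 and 307 CPM in heat pools 1, 2 and 3, while HSF1 overlaps between the groups.

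Other genes of protein folding showed smaller differences. HSPA5, the main HSP70 of the endoplasmic reticulum, was at 0.87 (SE 0.22, edgeR adjusted p = 0.128) and HSP90B1, its HSP90, at 0.58 (SE 0.15, edgeR adjusted p = 0.133). The list of the unfolded protein response of the endoplasmic reticulum had a median of 0.18 over 33 members and a camera adjusted p of 0.023 (adjusted p = 0.998 with an estimated correlation), and 0 members passed over the list alone. The median by pool was 0.026 in heat pool 1, below the 0.058 of control pool 3. The camera call was lost without control pool 1, control pool 2 or heat pool 3 (median 0.12), and the count over the list alone was 5 without heat pool 1 and 3 by DESeq2. HSF1, the transcription factor of the heat shock response, was at 0.21 (SE 0.28), and HSP90AB1 was at -0.60 (SE 0.23, edgeR adjusted p = 0.222). HSP90AB1 was listed at 36.3 ± 6.64 CPM in control pools, against 614 ± 80.7 CPM for HSP90AA1, and its value is uncertain: reads shared with similar genes were not examined here. Among 12 subunits of the chaperonin and prefoldin, PFDN4 rose (0.47, SE 0.14) and PFDN2 (-0.43, SE 0.12) and PFDN1 (-0.48, SE 0.15) fell, adjusted over the list alone. That list had a median of 0.13 and a camera adjusted p of 0.85, and its count of 3 was 0 without any single pool other than heat pool 3, and 1 after removal of a trend on gene length.

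Sterol synthesis genes were lower in heat pools. Of 23 tested members, 22 had a negative fitted change and 18 fell with adjusted p under 0.05 adjusted over the list alone, while over all genes none passed in edgeR and 13 fell in DESeq2. SQLE, the squalene epoxidase, fell from 90.8 ± 19.3 to 31.7 ± 8.03 CPM (log2 fold change -1.52, SE 0.23). FDPS, the farnesyl diphosphate synthase, was at -1.36 (SE 0.23), CYP51A1, the lanosterol demethylase, at -1.26 (SE 0.23) and PMVK, the phosphomevalonate kinase, at -0.87 (SE 0.16), each with adjusted p under 0.05 over the list alone. The median of the list was -0.74 and its camera adjusted p was 2.40e-11, with an adjusted p of 0.998 (unadjusted 0.0888) with an estimated correlation. The list median lay below the control mean in every heat pool, at -0.72, -1.34 and -0.49. The count of 18 was 11 without control pool 3 and between 15 and 19 without any other single pool.

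**Figure D2:**
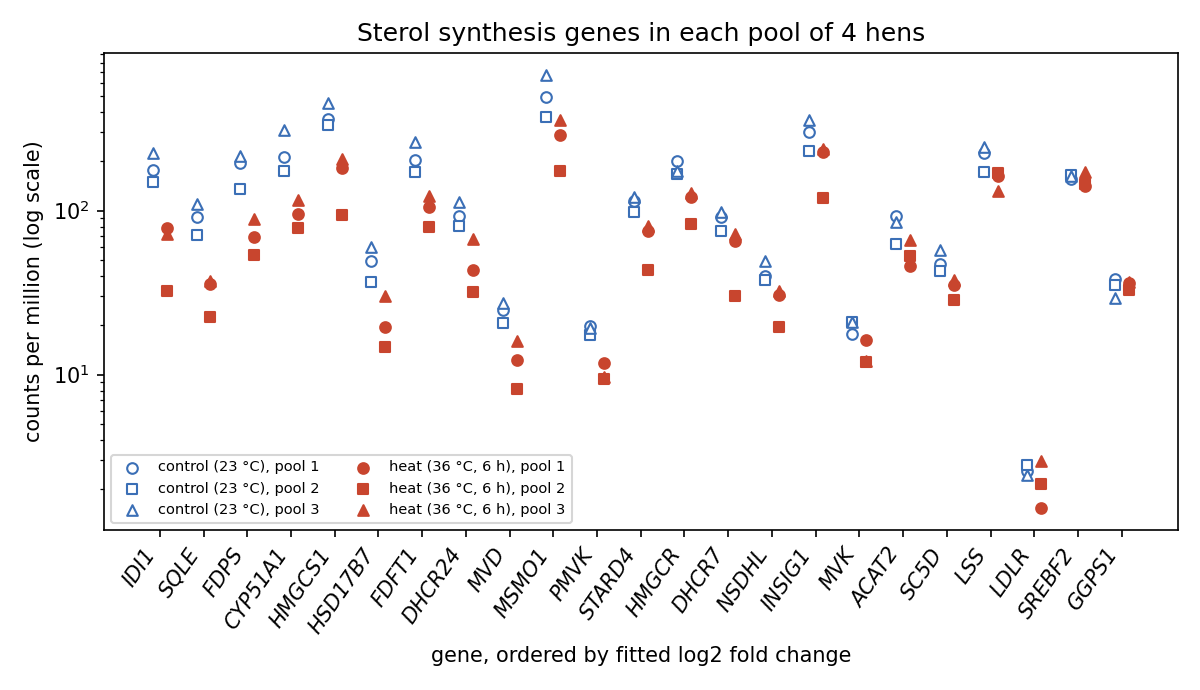
CPM (log axis) of the 23 tested sterol synthesis genes, one point per pool, with open blue symbols for the 3 control pools and filled red symbols for the 3 heat pools. In 18 of the genes every heat pool lies below every control pool.

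Some genes of fat handling were higher. Among 27 genes of lipid absorption and lipoproteins, 5 rose over the list alone, among them SOAT1, which esterifies cholesterol (0.75, SE 0.15), CD36, a fatty acid carrier (1.24, SE 0.27), and MTTP, which loads lipid onto apolipoprotein B (1.01, SE 0.23). The list had a median of 0.14 and a camera adjusted p of 0.0554, and passed camera without control pool 1 or heat pool 2 (adjusted p = 0.946 and 0.917 with an estimated correlation). The median was 0.24 and 0.32 without these 2 pools and 0.016 without heat pool 1. Its count of 5 was 0 without control pool 1, 0 without control pool 3 and 2 without heat pool 1. Among 24 genes of fatty acid oxidation and ketogenesis, 2 rose over the list alone: PDK4, which blocks glucose oxidation, from 17.6 ± 6.47 to 118 ± 75.5 CPM (2.75, SE 0.47), and PPARA, a fatty acid sensing nuclear receptor, from 67.1 ± 8.8 to 135 ± 31.4 CPM (1.01, SE 0.18). Both passed over the list alone without each pool in turn, and ETFA also fell without heat pool 3. Without heat pool 2 the log2 fold changes of PDK4 and PPARA were 2.1 and 0.84. The camera adjusted p of that list was 0.882, with a median of -0.028. The fructose transporter SLC2A5 fell (-1.18, SE 0.23), as 1 of 30 nutrient transporters, a list with a median of -0.0031 and a camera adjusted p of 0.998. That count of 1 was 0 without control pools 2 or 3 or heat pool 2; 1 member rose and 5 fell without heat pool 3, 1 rose and 1 fell without heat pool 1, and 1 rose and 2 fell by DESeq2.

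The list of cell cycle genes was lower in heat pools. Of its 46 tested members, 37 had a negative fitted change, and 11 fell and 0 rose over the list alone, with a median of -0.28 and a camera adjusted p of 7.86e-07 (adjusted p = 0.998 with an estimated correlation). RRM1 fell from 47.3 ± 4.73 to 23.9 ± 2.56 CPM. MCM5 (-1.07, SE 0.18) and MCM2 (-0.86, SE 0.15), of the replicative helicase, and TYMS (-0.63, SE 0.12), the thymidylate synthase, also fell over the list alone. The count of 11 was 6 without control pool 1 and 6 without heat pool 2, and between 8 and 10 without each of the others. Intestinal stem cell genes did not pass (17 members, 0 over the list alone, median 0.11, camera adjusted p 0.977), and their count was 1 without control pool 1, 2 without heat pool 1 and 2 by DESeq2. Their median turned to -0.12 without control pool 1 and to -0.21 without heat pool 2.

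Proteasome and respiratory chain genes had small negative changes. Of 36 proteasome and ubiquitin genes, 8 fell, among them the proteasome subunits PSMD14 (-0.50, SE 0.11) and PSMA5 (-0.50, SE 0.12), and 1 rose over the list alone. The list had a median of -0.30 and a camera adjusted p of 2.47e-06 (adjusted p = 0.998 with an estimated correlation). Its count of 9 was 28 without heat pool 3, 0 without any other single pool, 2 after removal of a trend on gene length and 26 by limma-trend on log2(FPKM + 1). Of 66 nuclear genes of oxidative phosphorylation, 63 had a negative fitted change and 0 passed over the list alone. Their median was -0.26, with a camera adjusted p of 5.44e-09 (adjusted p = 0.998 with an estimated correlation); UQCRQ was at -0.54 (SE 0.13) and ATP5O at -0.53 (SE 0.14). That count of 0 was 44 without heat pool 3, 4 by DESeq2 and 27 by limma-trend on log2(FPKM + 1). The list median was -0.021 in heat pool 3, within the control pools' -0.021 to 0.016, against -0.40 and -0.34 in heat pools 1 and 2, and was -0.14 after removal of a trend on gene length. The Spearman correlation across genes of a library's deviations with length was 0.273 and 0.242 in heat pools 1 and 2, -0.151 in heat pool 3, and -0.266, -0.0517 and -0.132 in control pools 1, 2 and 3. Across genes, which are not independent replicates, the Spearman correlation of log2 fold change with length was 0.226, and these lists are short (median 406 and 1031 bp, against 2547 bp for all tested genes).

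Interferon response genes were lower as a list, with overlap between the groups, and inflammation genes showed no common direction. Of 29 interferon response genes, 28 had a negative fitted change and 2 fell over the list alone: USP18, a negative regulator of interferon signalling, from 112 ± 49.9 to 26.9 ± 9.48 CPM (-2.06, SE 0.37), and OASL, an antiviral protein, from 221 ± 53.6 to 75.6 ± 35.6 CPM (-1.55, SE 0.34). The list had a median of -0.40 and a camera adjusted p of 1.87e-07 (adjusted p = 0.998 with an estimated correlation). The median by pool was -0.54, -0.76 and -0.19 in heat pools 1, 2 and 3 and -0.30, 0.12 and 0.15 in control pools 1, 2 and 3, and without heat pool 3 the list median was -0.76. Its count of 2 was 16 without control pool 1, 19 without heat pool 3, 0 without control pool 2 or heat pool 1, 1 without control pool 3, 8 by DESeq2 and 7 by limma-trend on log2(FPKM + 1). Among 44 genes of cytokines and Toll-like receptors, 0 passed over the list alone in edgeR and 2 in DESeq2 (median 0.0052, camera adjusted p 0.85).

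Clock genes changed in both directions. The hour at which each group was sampled is not given in the sources used here. Of 22 members, 5 rose and 3 fell over the list alone. CRY2 (1.16, SE 0.18), CRY1 (0.82, SE 0.15) and ARNTL (0.59, SE 0.11) rose and NR1D1, a repressor of ARNTL, fell from 3.9 ± 0.527 to 1.01 ± 0.306 CPM (-1.93, SE 0.31). The count of 8 stayed between 8 and 9 without each pool in turn, and the list had a median of 0.028 and a camera adjusted p of 0.882. Glucocorticoid responsive genes had a median of 0.21 (0.11 by limma-trend on log2(FPKM + 1) and 0.12 after removal of a trend on gene length) and a camera adjusted p of 0.048 (adjusted p = 0.998 with an estimated correlation), and 3 of 25 rose over the list alone: PDK4, the mineralocorticoid receptor NR3C2 (0.60, SE 0.13) and TSC22D3 (from 116 ± 17.8 to 232 ± 83 CPM). That count of 3 was 1 without control pool 2, 1 without control pool 3, 5 without heat pool 1 and 9 without heat pool 3 (with 1 lower in each), 1 by limma-trend on log2(FPKM + 1) and 7 (with 1 lower) after removal of a trend on gene length, and the camera call was lost without control pool 2, heat pool 1 or heat pool 2.

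In the list of hypoxia and glycolysis, 4 of 30 genes rose and 2 fell over the list alone. EGLN3, a prolyl hydroxylase (0.86, SE 0.13), and NDRG1 (1.77, SE 0.30) were among those that rose, and PGAM1, a glycolytic mutase, fell (-0.48, SE 0.12). The list had a median of -0.030 and a camera adjusted p of 0.85, and its count of 6 was 2, 2 and 3 without control pools 1, 2 and 3, 4 without heat pool 1 and 10 without heat pool 3. Of 35 antioxidant genes, GPX1 (1.05, SE 0.25), GCLC (0.57, SE 0.14) and CAT (0.49, SE 0.13) rose and GPX2 fell (from 57.6 ± 9.6 to 28.8 ± 8.73 CPM) over the list alone, with a median of 0.051 and a camera adjusted p of 0.882. That count of 4 was 0 without any single control pool or heat pool 1, 1 without heat pool 2 and 2 by limma-trend on log2(FPKM + 1). Immediate early genes (29, median -0.11, camera adjusted p 0.85) and apoptosis genes (33, median 0.067, camera adjusted p 0.559) had 0 members past the threshold over the list alone, and 3 and 1 without heat pool 1. For the immediate early list the count was also 1 without heat pool 2, 4 by DESeq2 and 2 after removal of a trend on gene length.

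Epithelial genes and markers of other cell types did not pass as lists. Over the list alone 0 genes passed among 22 brush border and digestive genes (median 0.025, camera adjusted p 0.882), 25 junction genes (median 0.098, camera adjusted p 0.231), 12 goblet cell genes (median 0.13, camera adjusted p 0.906) and 24 enteroendocrine genes (median 0.057, camera adjusted p 0.906). The same was true of 28 T and NK cell genes (median 0.11, camera adjusted p 0.346), 18 B and plasma cell genes (median -0.23, camera adjusted p 0.906) and 26 myeloid genes (median 0.019, camera adjusted p 0.882). It was also true of 24 smooth muscle genes (median 0.12, camera adjusted p 0.231), 24 fibroblast genes (median 0.053, camera adjusted p 0.977), 13 neuron and glia genes (median 0.079, camera adjusted p 0.977) and 21 endothelial genes (median -0.097, camera adjusted p 0.906). Of 5 erythroid genes, the carbonic anhydrase CA2, which other cells also make, rose (0.99, SE 0.13) and the haemoglobin HBBA fell from 12.2 ± 1.68 to 6.2 ± 0.335 CPM over the list alone (median -0.13, camera adjusted p 0.998). Without a single pool some of these counts of 0 moved: without heat pool 1, 5 smooth muscle and 2 goblet cell genes passed, without control pool 1, 4 myeloid genes and 1 B cell gene, without control pool 3, 1 enteroendocrine gene, and without heat pool 3, 1 junction, 1 brush border and 1 goblet cell gene. DESeq2 gave 2 junction genes, 1 enteroendocrine gene and 1 smooth muscle gene. Camera passed the T and NK cell list without control pool 2 or heat pool 2, the smooth muscle list without control pool 3 or heat pool 1, the junction list without heat pool 1, the fibroblast list without heat pool 2 (median -0.22) and the brush border list without heat pool 3 (median -0.22). With an estimated correlation the adjusted p of these calls lay between 0.847 and 0.995. For the lists of brush border, nutrient transport, fatty acid oxidation, stem cells, clock, hypoxia, myeloid and erythroid genes, the median, the mean and the direction of the test differed in sign.

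**Figure D3:**
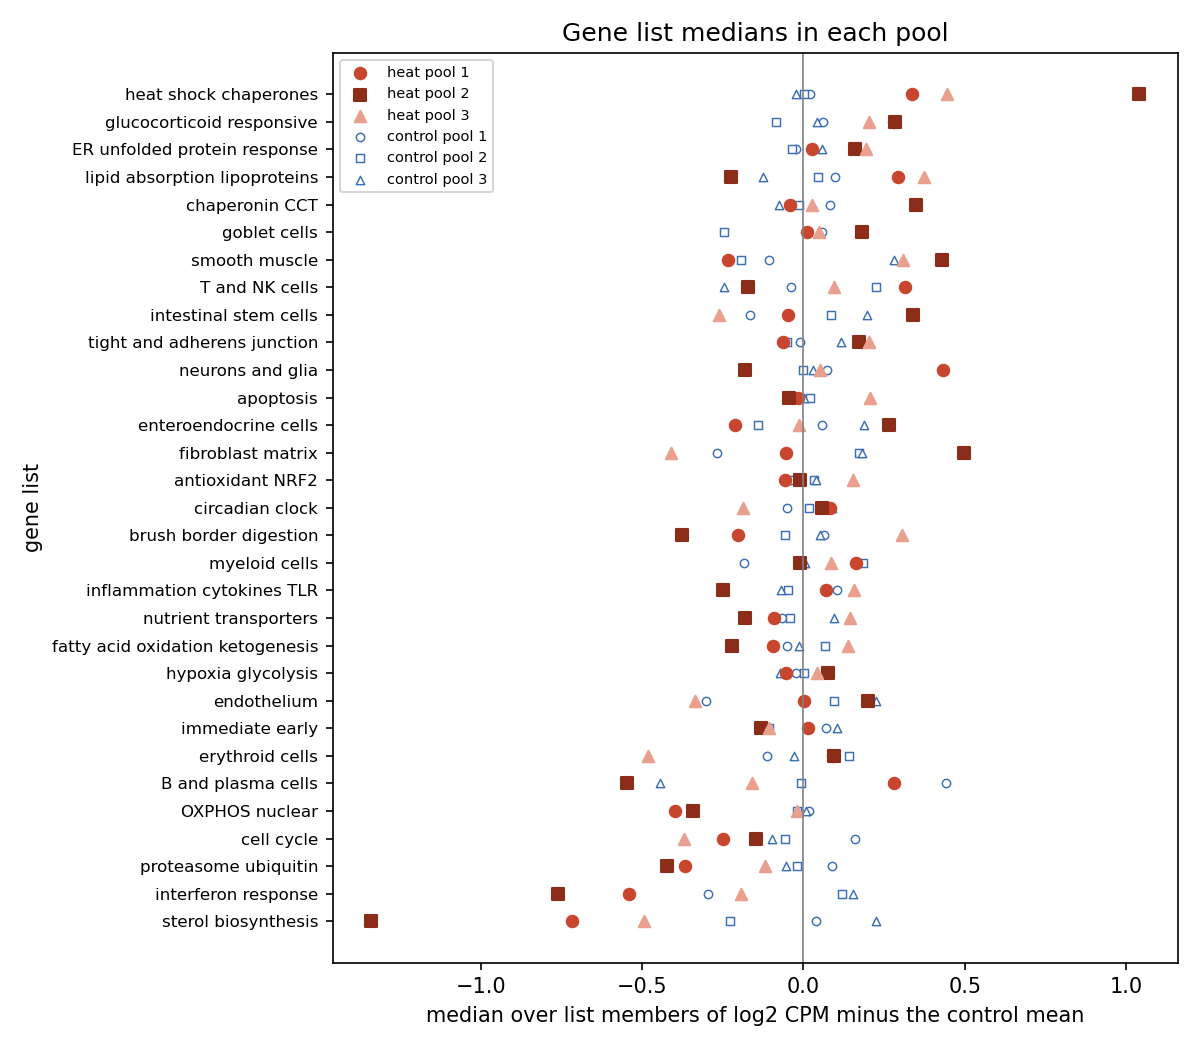
Median over the members of each gene list of the log2 CPM minus the control mean, with red symbols for the 3 heat pools and open blue symbols for the 3 control pools. Heat shock chaperones lie highest in heat pool 2 (1.04) and sterol synthesis genes lowest there (-1.34).

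The gene test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13060 genes, and camera was adjusted over 31 lists, of which 8 passed with the preset correlation and 0 with an estimated one. With an estimated correlation all 31 lists shared the adjusted p of 0.998, which does not rank them. Unadjusted camera p by that estimate was 0.0746 for glucocorticoid, 0.0888 for sterol synthesis, 0.171 for cell cycle and 0.194 for chaperone genes. It was 0.2 for interferon, 0.239 for proteasome, 0.285 for unfolded protein response and 0.296 for respiratory chain genes. Other groupings of the same 6 libraries gave between 6 and 14 lists by the same camera test and at most 1 gene by edgeR.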

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

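The count of 3 genes came from edgeR on rounded estimated counts, and limma-trend on log2(FPKM + 1) was the plan's test without raw counts. Voom with quality weights, a mean FPKM of at least 1, library totals and removal of the length trend were chosen after seeing the data. OSGIN1 and IRS2 were called in every edgeR setting with all 6 libraries, and CYP2U1 in all of these but library totals. The count was 203 at an adjusted p under 0.1, 5 with a mean FPKM of at least 5, and 5 (all 5 at least 2-fold) with voom quality weights. DESeq2 called 615 genes, 143 of them at least 2-fold, and gave no adjusted p for HSPA2 and HSPB9. Limma-trend on log2(FPKM + 1) called 41 genes (12 higher and 29 lower), 21 of them at least 2-fold. From that fit, a pseudocount of 0.1 gave 1 (1 at least 2-fold), 0.5 gave 37 (21), no filter 0 (0), a mean FPKM of at least 5 gave 70 (26), quantile normalization 1 (1), no trend 0 (0) and robust moderation 86 (37). Median-ratio factors gave 3 (3) and rescaling to TPM gave 3 (2), with 0 lower in each, so the larger share of lower genes depended on the scaling. Without each library in turn, both counts ranged from 0 to 7. The lists past the threshold by camera numbered 7 to 10 across these settings, and 0 with an estimated correlation and 0 with fry. An estimated correlation also gave 0 without each library in turn and after removal of the length trend, both run after seeing the data. Chaperone, sterol, interferon, cell cycle, respiratory chain and proteasome lists passed camera in all 26 settings with the preset correlation, the unfolded protein response in 23 and the glucocorticoid list in 20. The median of the fibroblast list reversed to -0.22 without heat pool 2, and that of the brush border list to -0.22 without heat pool 3; across the left-out pools they ranged from -0.22 to 0.26 and from -0.22 to 0.079. The median of 15 of the 23 lists that did not pass camera turned in sign without at least 1 pool, among them stem cells (-0.21 to 0.21), and that of 0 of the 8 that passed. Over the list alone, limma-trend gave 3 chaperones, 20 sterol synthesis genes, 26 proteasome and 27 respiratory chain genes. Where not stated, the cause was not tested.

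The replicate number as a block gave 23 genes (22 at least 2-fold) in edgeR and 15 (15) in limma. The labels do not say that equal numbers pair the samples, and the values leave it open. Deviations of same-numbered pools correlated at 0.257, 0.0891 and 0.0169. Heat pool 1 correlated best with control pool 1, and heat pool 2 with control pool 3 (0.185). Heat pool 3 also correlated best with control pool 3, but hardly more than with control pool 1 (0.0129).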

Other observations

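Of the tests below, those of library depth, of the heat shock genes named in advance, of the surface epithelium and of the edgeR counts over other splits were chosen only after the result was seen. The genes of the next paragraph were also chosen after their values were seen.

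Some single genes outside the fixed lists stood near the threshold, each with an edgeR adjusted p of 0.0773. They were picked by name from the 203 genes with an adjusted p under 0.1 and form no tested group. The RNA helicase DDX3X, already abundant, was at 1597 ± 39.4 CPM in control pools and 4648 ± 1059 CPM in heat pools (log2 fold change 1.54, SE 0.21). CIRBP, the cold inducible RNA-binding protein, was at 370 ± 22.5 and 167 ± 37.3 CPM (-1.15, SE 0.17), and HNRNPD, which binds AU-rich messenger RNA, at -0.98 (SE 0.15). FBXO32, a ubiquitin ligase of muscle wasting, was at 0.95 (SE 0.14) and DIO1, a deiodinase of thyroid hormone, at -1.01 (SE 0.17).

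Heat pool 2 held far more chaperone messenger RNA than heat pools 1 and 3, with a median excess of 0.698 (log2, bootstrap 95% interval 0.549 to 1.08). The bootstrap here and below resampled the genes of a list and not the pools. Its intervals and bounds hold no spread between hens or pools, and they treat genes that vary together as independent. The total of heat pool 2, 12.78 M counts, lay within the range of the other 5 libraries. The excess was calculated on log2 CPM, which is already scaled for library depth, so this total could not decide on depth as a source. A different tissue mix in this pool remains open: the fibroblast list had a median excess of 0.682 with an upper bound of 0.733, which reaches the chaperone median. For the 10 heat shock genes named in advance the median excess was 1.51 (2.85-fold, against 1.6-fold for the fibroblast list). Its lower bound of 0.698 lies under 0.733, so their median cannot tell a mix from a stronger response. Single genes differed: 7 of the 10 exceeded 0.733 and the rest did not. A stronger heat response in some of its 4 hens may also be the source, and pooling leaves this untested.

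Lower sterol synthesis may reflect lower feed intake in the heat, which the labels do not record. A list of fasting-induced genes was written after the main results. IRS2, PDK4, PPARA and FBXO32, already seen to be higher, are not in it. Of its 24 genes, 9 are also in other lists, whose values had been calculated before, and the remaining genes were not tested alone. The median was 0.252 (camera p 0.000383, and p 0.017 with an estimated correlation, both unadjusted), with KLF15 at 1.03 and INSR at 0.78. This goes in the direction of that idea, but it comes from the same libraries as the idea and is no independent test. Fatty acid synthesis genes, which feeding also drives, had a median of -0.0706 (camera p 0.156), with AACS and ACLY lower over the list alone, and leave the idea undecided. Brush border genes, whose lower bound of -0.176 lies above the upper bound of the sterol list, -0.568, argue against loss of the surface epithelium as the whole source. Their medians were -0.20, -0.38 and 0.30 in heat pools 1, 2 and 3, against -0.72, -1.34 and -0.49 for the sterol list. In heat pool 3 the sterol median was thus lower without a lower brush border median, but single brush border genes differed. Of the 22 tested, 4 (VIL1, ESPN, MYO1A and EZR) lay below every control pool in every heat pool, and 0 lay above. VIL1 was at 1106 CPM in heat pool 3, against 1200 to 1267 CPM in the control pools. A part played by such a loss therefore remains open in every heat pool. Heat itself and feed intake cannot be separated in this design.

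Lower respiratory chain and proteasome genes could come from a trend on gene length, since the Spearman correlation of each library's deviations with length was -0.266, -0.0517 and -0.132 in control pools and 0.273, 0.242 and -0.151 in heat pools. After removal of that trend the proteasome median went from -0.295 to -0.204 (bootstrap 95% interval -0.304 to -0.15), more than 50% of its size. Camera then gave an adjusted p of 9.09e-05 with the preset correlation and 0.933 with an estimated one, and members past the threshold over the list alone went from 9 to 2. The respiratory chain median went from -0.258 to -0.139 (-0.166 to -0.123), so an interval that spans 50% leaves the length trend open there. Ribosomal protein genes (median implied length 261 bp) had a lower bound of 0.0387, above the upper bound of the respiratory chain list, -0.232. They argue against a loss of all short transcripts alike. As a single family they cannot decide on a general trend, and across genes the log2 fold change rose with length (Spearman correlation 0.226). A biological decline of respiratory chain or proteasome genes was not tested separately.

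The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past the threshold in edgeR, and for those also at least 2-fold, 1 split gave as many (real 3, highest other 1). For DESeq2 it was also 1 split (real 615, highest other 43). For lists by camera with the preset correlation, 8 of the 10 splits gave as many (real 8, highest other 14). With an estimated correlation, 0 lists passed in any of the 10 splits; that correlation was 0.378 for chaperones, 0.525 for sterol synthesis and 0.68 for the respiratory chain, against the preset 0.01. Counts over the list alone were 18 for chaperones, 18 for sterol synthesis, 11 for the cell cycle and 8 for the clock in the real split, with a highest other of 0 for each of these 4 lists. For interferon genes the real count was 2 and the highest other 15, and for smooth muscle 0 and 12.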
